A study of Mus musculus with 15 samples.

How the data were processed

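The microarrays were scanned by the authors and read with Feature Extraction 11.5.1.1 and protocol GE1_1105_Oct12, per the file headers. Each of the 15 deposited array tables held 62976 spots, of which 59305 were not controls and belonged to 55681 probes. The value taken from each table was the processed green signal, an intensity in arbitrary units that the authors' software had already corrected for background. That intensity was turned into log2 here, the spots of one probe were averaged, and the 75th percentile of the non-control probes of the array was subtracted. Values below are therefore log2 signal relative to the array's 75th percentile. Spots that the software had marked as differing from their replicate spots were left out of the averages, and no spot was saturated. The authors' own normalized values, which are log2 per the labels, correlated with the values used here at 1 on every array, and their 75th percentiles lay near 0.

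Gene symbols came from the RefSeq accessions of the probes, because the array tables used here gave no gene names. Of the 55681 probes, 28331 received a symbol, for 21368 different genes, and 27350 had none. A probe was kept if the software called it well above background on all 3 arrays of at least 1 group, which 29782 probes were, 18931 of them with a symbol. The brightest passing probe over all 15 arrays stood for its gene, which gave 14443 genes, 3735 of them with more than 1 passing probe.

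One limma model with a mean for each of the 5 groups was fitted to the 15 arrays, with 10 residual degrees of freedom and moderated t-tests, which are two-sided. P-values were adjusted over the 14443 genes of a comparison by the Benjamini-Hochberg method. A gene was called when its adjusted p was under 0.05 and it differed at least 1.5-fold. The words rose and fell are kept for called genes and for gene lists that passed the list test. Values after a plus-minus sign are standard deviations over 3 arrays, and SE is the standard error of a log2 difference. Where a gene was not well above background on every array of the lower group, its fold is given as a bound. For the bound, values of the lower group were raised to the lowest value that was well above background on the same array. Such folds are written as at least so many fold.

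The groups, the 6 comparisons, the 20 gene lists with 330 members, the rules for naming genes and most of the alternative settings were chosen before the data were examined. Of the 330 list members 294 were measured. The lists were naive pluripotency, general pluripotency, formative and primed state, ERK targets, NF-kB targets, and AP-1 and stress kinase targets. Lists of other lineages and states were primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, 2-cell-like state and germline. The others were fibroblast and feeder markers, interferon response, ATF4 targets, cholesterol synthesis, glycolysis, proliferation, p53 targets and cap-binding translation initiation factors. Each list was tested with camera, with a fixed correlation of 0.01 between genes, and its p was adjusted over the 20 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. For the members of a list, counts are given from the adjustment over all genes, and also adjusted over the list alone where that count differs. The members' median change, their mean change and the test differed in sign in 24 of the 120 list tests, none of them called.

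Genes were named by fixed rules. The targeted gene, Map3k3, any probe for EGFP and the N-acetyltransferase gene that shares the symbol Nat1 were always looked up. For the null cells against wild-type cells, and for the genes that responded to Map3k3, the 10 rising and 10 falling called genes with the largest change were named, and 5 each way elsewhere. The rule orders genes by their measured log2 difference, signals near background included, so the named genes are not an order by fold or by bound, and genes outside the rule can have larger bounds. Genes known only by a clone or locus name were passed over, and 1 gene that the rule names is not reported here. List members serve as further examples. For null against wild-type cells the rule itself took only genes in which the arrays of the groups did not overlap. In the other genes named for the size of their change the arrays compared did not overlap either, except Npy in Map3k3 cells with against without Dox.

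The recovery score placed each array on the line from the mean of the null arrays, at 0%, to the mean of the wild-type arrays, at 100%, over the 5526 genes called between those groups. Scores were compared by exact permutation of arrays, two-sided.

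The labels number the arrays of each group from 1 to 3. Whether equal numbers belong together was checked by correlating the deviations of arrays from their group means over all genes. For Map3k3 with against without Dox the correlations of equal numbers were 0.154, 0.318 and 0.252, and for Map3k3 against EGFP with Dox 0.101, 0.316 and 0.193. For the null cells they were 0.251, 0.561 and 0.383 with EGFP with Dox, and 0.270, 0.617 and 0.411 with Map3k3 without Dox. With wild-type cells they were -0.03, 0.0084 and 0.0054 for the null cells, and 0.047, 0.0591 and 0.0082 for Map3k3 with Dox. Equal numbers therefore shared deviations within the 4 null-background groups and not with wild-type cells. The main model did not use the numbers, and a model that did is given where it changes a result.

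The arrays lay on 2 slides, in 2 rows each. Slide 2 held the wild-type arrays and EGFP with Dox 3 in row 1, and the null arrays in row 2. Slide 1 held Map3k3 without Dox and Map3k3 with Dox 1 in row 1, and Map3k3 with Dox 2 and 3 and EGFP with Dox 1 and 2 in row 2.

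The model was tested on simulated data with the real genes' means and spreads and with changes put into 100 genes per size. It recovered 81, 76, 75, 75, 86 and 81% of the 2-fold changes in the 6 comparisons. Of the 4-fold changes it found 96, 93, 93, 96, 97 and 97%. False calls numbered 9, 7, 5, 2, 8 and 8 of 14443 genes. The simulated noise was independent between genes and between arrays. It had no slide, slide row or replicate number effects and no background floor, so these rates hold only for such noise. Most alternatives changed 1 choice, and those with slide and slide row as blocks, or with a block on part of the arrays, changed more than 1. They were normexp background correction on the median signal of each spot, quantile normalization, the authors' normalized values, other filters, the mean of a gene's probes, a model on the groups of 1 comparison alone, other fold minimums, blocks for slide, slide row and replicate number, and leaving out each array. Normexp thus also replaced the processed signal, and the median was used because the array tables used here gave no mean signal. No genome sequence was used here, and probe positions are those of the file headers on the mm9 build. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with matplotlib 3.10.9.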

Results

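Gene expression was measured with single-colour Agilent microarrays in mouse embryonic stem cells of 5 groups, with 3 arrays each. The groups were wild-type cells, cells without the gene called Nat1 in the labels (null cells), and 3 groups of null cells with a transgene that doxycycline (Dox) switches on. Of these, Map3k3 cells were grown with and without Dox and EGFP cells with Dox. Map3k3 is a kinase upstream of MAP kinase pathways, and EGFP, a fluorescent protein, serves as the control transgene. The labels do not say that the 3 samples of a group are separate cultures, so p-values measure only the spread between these samples. The 75th percentile of signal per array lay between 556 and 696 units, and 42.7 to 53.9% of probes were well above background. The lowest share was that of Map3k3 with Dox 2, whose lowest signal of 12.7 units was also the highest of all arrays. Both measures differed by slide row. In row 1 the shares were 50.8 to 53.9% and the lowest signals 4.33 to 4.83 units. In row 2 they were 42.7 to 49.2% and 6.12 to 12.7 units. Wild-type arrays lay in row 1 and null arrays in row 2, so detection and bounds differ with row between them. Within groups, correlations between arrays across genes, which are not independent replicates, had a lowest value of 0.9855. Precision is limited by the number of arrays.

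The gene called Nat1 in the labels is now named Eif4g2 and encodes a relative of the translation initiation factor eIF4G. Its signal was 4.13 ± 0.14 in wild-type cells, 1.56 ± 0.20 in null cells, 1.46 ± 0.15 in Map3k3 cells without Dox, 1.43 ± 0.06 in Map3k3 cells with Dox and 1.40 ± 0.26 in EGFP cells with Dox (log2, SD, n = 3). It fell 5.95-fold in null cells (log2 change -2.57, SE 0.14, adjusted p = 2.15e-08). Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so the remaining signal is not read as intact transcript. The gene whose symbol is Nat1 today, an arylamine N-acetyltransferase, is unrelated. Its probe read -4.44 in wild-type cells, was well above background on 2 of those 3 arrays and on no other array, and did not pass the filter. The Map3k3 probe read -0.68 ± 0.15 in Map3k3 cells with Dox, -0.85 ± 0.23 without Dox and -0.93 ± 0.10 in EGFP cells. Its differences of 0.17 (adjusted p = 0.279) and 0.25 (adjusted p = 0.107) were not called. Whether the probe matches the transgene is not given in the sources used here, so it does not check the induction. No probe for EGFP was found.

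**Figure D1:**
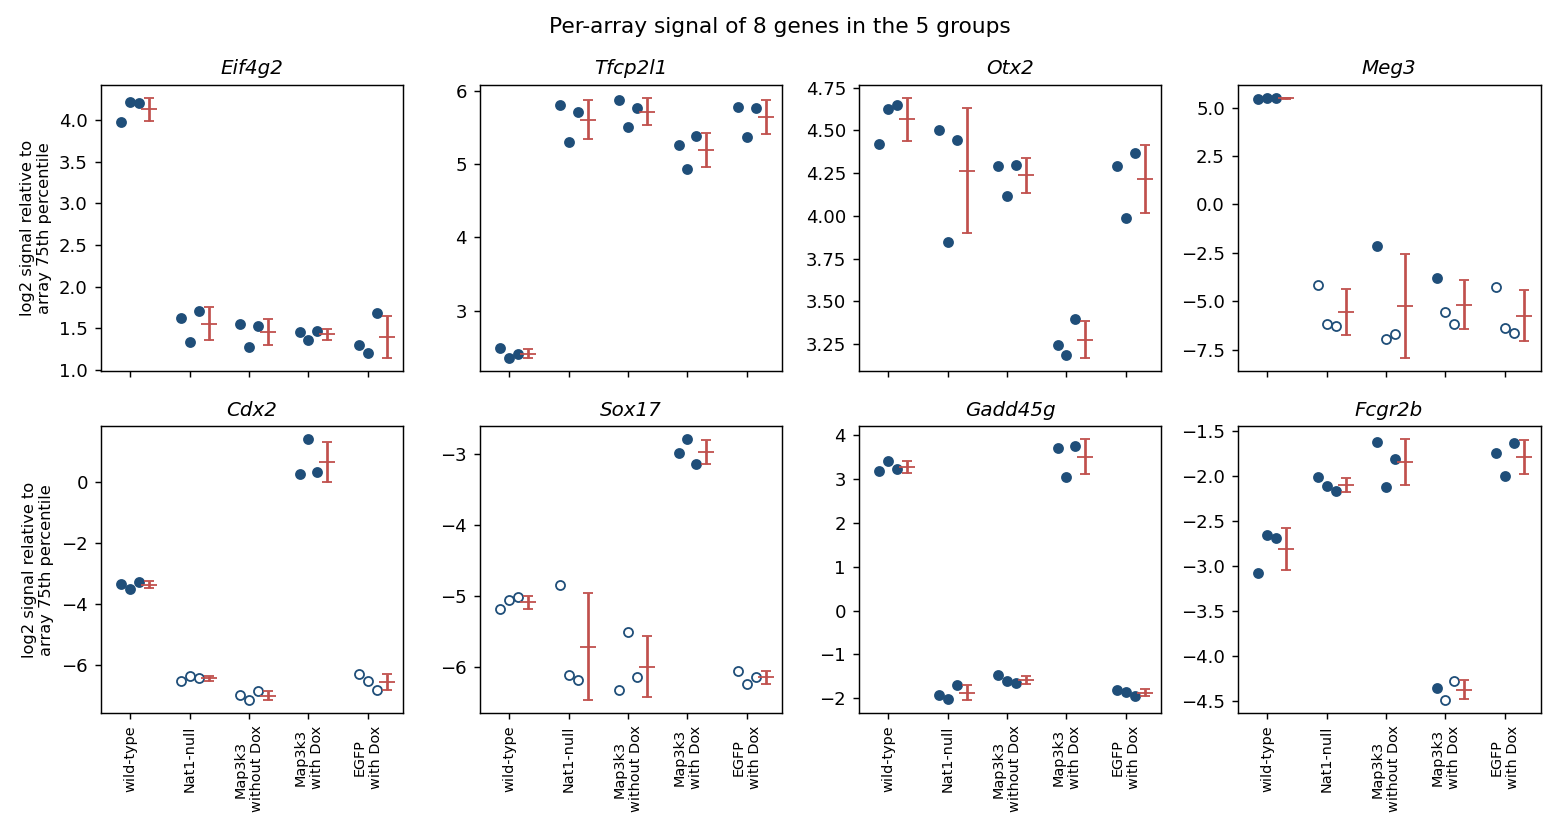
Log2 signal relative to the array's 75th percentile (y axis) of 8 genes in the 5 groups (x axis), with a point per array, filled where well above background and open where not, and bars at the mean with its standard deviation over 3 arrays. Eif4g2 reads 4.13 in wild-type cells and 1.40 to 1.56 in the 4 other groups, and Cdx2 and Sox17 are highest in Map3k3 cells with Dox.

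The first comparison sets null cells beside wild-type cells. The labels do not say that the null cells were derived from these wild-type cells. Loss of the gene and other differences between the lines therefore cannot be told apart in it. Of 18 naive pluripotency genes 13 rose in the null cells, with Klf4 9.75-fold and Tfcp2l1 9.11-fold higher, and the list had adjusted p = 0.0693 with an estimated correlation. Of 15 genes of the formative and primed state 10 fell, among them Fgf5 at least 16.3-fold and Dnmt3a 8.38-fold, and the list had adjusted p = 0.222 with an estimated correlation. The trophectoderm keratin genes Krt8, Krt18 and Krt19 and the neural genes Nefl and Nes fell as well, as did several imprinted genes, Meg3 at least 929-fold and H19 at least 945-fold. In limma, 5526 of 14443 genes were called, of which 2640 rose and 2886 fell. With no fold minimum 5309 were higher and 3942 lower, and with probes above background on all 15 arrays 2407 and 1531, so the majority direction depends on these choices. The 3 arrays of the groups did not overlap in 72.9% of all genes, where chance gives 10%. Of the 5526 calls, 1329 have only a bound for their fold and 40 have no fold, since neither group was far enough above background.

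The genes that the naming rule gives for a rise encode transcription factors, signalling proteins and membrane proteins. The homeobox genes Nkx6-3 and Tlx2 rose 189-fold (log2 change 7.56, SE 0.31, adjusted p = 2.66e-09) and at least 36.9-fold. The neuronal membrane protein gene Islr2 rose 54.3-fold (log2 change 5.76, SE 0.19, adjusted p = 3.98e-10), and Inhbb, an activin subunit, 52.1-fold (log2 change 5.70, SE 0.43, adjusted p = 3.52e-07). Fxyd4, a regulator of ion pumps, rose 24.1-fold. Genes of small GTPase signalling were Rapgef3, 21.7-fold higher, and Mras, 17.4-fold (log2 change 4.12, SE 0.11, adjusted p = 9.02e-11). The phosphatase regulator Ppp1r14d rose 18.0-fold and the zinc finger gene Zbtb7c at least 9.93-fold.

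Of the 10 genes that the naming rule gives for a fall, 4 are imprinted. These are the non-coding RNA genes Meg3 (adjusted p = 5.38e-06), H19 (adjusted p = 1.55e-07) and Mirg, which fell at least 108-fold, and Snrpn, which fell at least 271-fold. The guanylate-binding protein gene Gbp2 fell at least 128-fold and the collagen gene Col1a2 at least 129-fold. The matrix protein gene Thbs1 fell at least 79.2-fold, Enpp2, which encodes the secreted enzyme autotaxin, at least 68.0-fold, the serine protease gene Prss23 at least 51.1-fold and the acyltransferase gene Mogat2 at least 45.3-fold.

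Of the 18 measured naive pluripotency genes, 13 rose, 3 fell and 2 were not called, in counts equal when adjusted over the list alone, as for every list of this comparison. The list rose with a median log2 change of 0.94 (camera, adjusted p = 0.00285), and had adjusted p = 0.0693 with an estimated correlation. The transcription factor genes Tbx3, Gbx2, Prdm14, Klf5, Nanog and Esrrb rose 15.1-, 7.14-, 5.50-, 4.12-, 2.43- and 2.23-fold. Against the list, Dppa3 fell 41.6-fold, Fbxo15 1.81-fold and Klf2 1.57-fold, while Pecam1 (log2 change -0.45) and Tdh (0.47) were not called. The general pluripotency list was not called (adjusted p = 0.241), with 6 of 14 members higher, such as Sox2 3.30-fold and Fgf4 2.03-fold, and Lin28b lower by 7.37-fold.

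The formative and primed list fell with a median log2 change of -2.40, or -2.22 with genes near background at their bound (adjusted p = 0.00285, adjusted p = 0.222 with an estimated correlation). Of 15 measured members 10 fell, 1 rose and 4 were not called. The cadherin gene Cdh2 fell 32.1-fold, Sall2 at least 17.2-fold, Pou3f1 5.28-fold and the DNA methyltransferase gene Dnmt3b 4.65-fold. Foxd3 rose 4.76-fold. Otx2 (-0.30), Sox3 (-0.46), Nodal (0.02) and Grhl2 (0.02) were not called.

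Of the 6 lists of other lineages and states, trophectoderm and neuroectoderm fell and the other 4 were not called. In the trophectoderm list 10 of 12 measured genes fell and 2 rose (adjusted p = 0.00448, adjusted p = 0.341 with an estimated correlation). Krt18, Krt8 and Krt19 fell 14.7-, 7.62- and 7.20-fold, whereas Tead4 and Tfap2a rose 3.35- and 2.62-fold. In the neuroectoderm list 10 of 14 fell and 1 rose (adjusted p = 0.00609, adjusted p = 0.228 with an estimated correlation), with Nefl lower by 18.1-fold, Sox11 by at least 17.9-fold and Nes by 9.91-fold, and Ncam1 higher by 5.09-fold. The primitive endoderm list was not called (adjusted p = 0.0603), with 9 of 16 genes lower, such as Lamb1 5.20-fold and Dab2 at least 4.29-fold, and 3 higher, such as Sox7 8.86-fold and Lama1 3.47-fold. Nor was the mesendoderm list (adjusted p = 0.0599), in which 6 of 14 genes fell, T at least 11.2-fold, and 2 rose. In the 2-cell-like list (adjusted p = 0.0811) 5 of 9 fell, Zscan4f at least 22.4-fold, and 1 rose. The germline list had 2 genes higher, 3 lower and 9 not called (adjusted p = 0.413).

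The list of fibroblast and feeder markers fell together with these lineage genes (adjusted p = 5.05e-05, adjusted p = 0.0693 with an estimated correlation). Of its 13 measured genes 9 fell and none rose, with Acta2 lower by at least 116-fold, Col1a1 by 53.4-fold and Tagln by 21.5-fold. Col3a1 (0.40), Col5a1 (-0.49), Loxl1 (-0.56) and Vim (-1.03) were not called.

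Signalling targets moved both ways. Among 21 ERK targets 7 fell, 3 rose and 11 were not called (adjusted p = 0.342). The phosphatase gene Dusp4 fell 13.5-fold, Egr1 3.08-fold and Fos 2.22-fold, and Etv4 rose 3.53-fold, Dusp6 1.59-fold and Spry2 1.55-fold. Of 15 AP-1 and stress kinase targets 8 fell and 3 rose (adjusted p = 0.0546), with Gadd45g lower by 35.5-fold and Atf3 by 3.22-fold, and Hspb1 higher by 2.38-fold. Of 13 NF-kB targets 4 rose, among them Nfkbie 4.74-fold and Nfkb1 2.87-fold, and 3 fell, among them Tnfaip3 2.37-fold (adjusted p = 0.241). In the interferon response list 5 of 8 fell, Isg15 9.78-fold, and 1 rose (adjusted p = 0.0546).

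The ATF4 target list fell (adjusted p = 0.0276, adjusted p = 0.463 with an estimated correlation), with 11 of 19 genes lower, such as Phgdh 5.27-fold and Stc2 4.01-fold, and 2 higher, including Atf4 itself 1.67-fold. The cholesterol synthesis list rose (adjusted p = 0.0368, adjusted p = 0.463 with an estimated correlation), with 4 of 17 genes higher, Cyp51 2.33-fold. So did the proliferation list (adjusted p = 0.0368, adjusted p = 0.341 with an estimated correlation), with 2 of 16 genes higher. With quantile normalization these 2 lists had adjusted p = 0.121 and 0.14 and were not called, and over all alternatives they ranged from 4.74e-05 to 0.463 and from 3.01e-06 to 0.341. The p53 target list was not called (adjusted p = 0.203). Its median change was 0.02 while the test pointed down, and 5 of 16 genes fell, Plk2 4.06-fold, and 1 rose. Glycolysis genes were 2 higher, 4 lower and 11 not called (adjusted p = 0.661), with Hk2 higher by 2.28-fold. Among 13 cap-binding initiation factors Eif4g3 fell 2.91-fold and Eif4b 1.61-fold, a further 1 fell, and Eif4e2 and Eif4a2 rose 1.90- and 1.64-fold (adjusted p = 0.709).

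The null and wild-type arrays lay on 1 slide but in different rows. With slide row as a block, where the Map3k3 cells with Dox and the EGFP cells have arrays in both rows, 4987 genes were called. Of these 50.7% rose, against 47.8% without the block, so the majority direction turned here too.

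**Figure D2:**
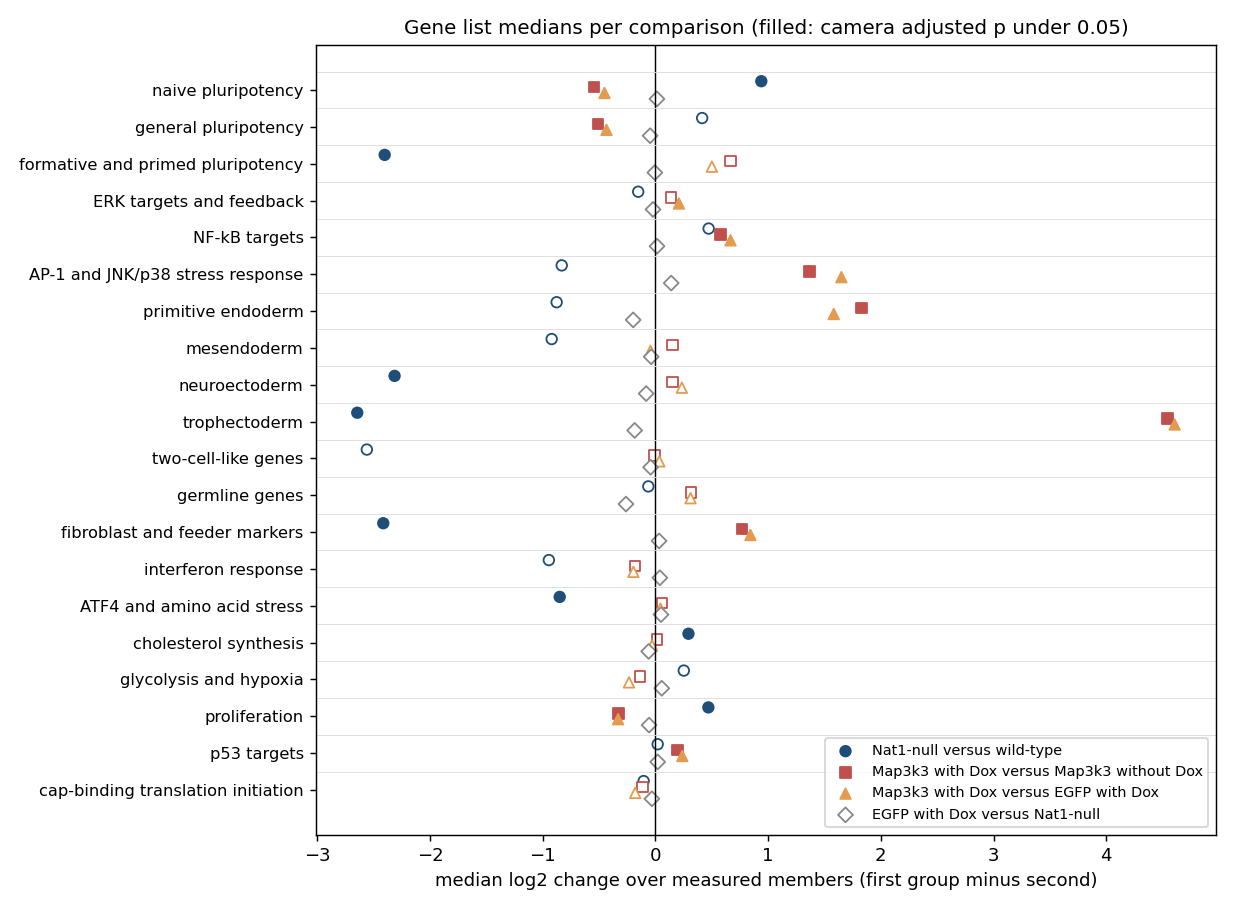
Median log2 change (x axis) of the 20 gene lists (y axis) in 4 comparisons, with filled points where the camera test had an adjusted p under 0.05. The formative and primed list has a median of -2.40 in null against wild-type cells, and the trophectoderm list 4.54 in Map3k3 cells with against without Dox.

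The next comparisons ask what Map3k3 does in null cells, with Map3k3 cells without Dox and EGFP cells with Dox as controls. Of 12 trophectoderm genes 11 rose with Map3k3 against cells without Dox (adjusted p = 0.057 with an estimated correlation) and 10 against EGFP cells (adjusted p = 0.0793 with an estimated correlation). Cdx2 rose at least 55.2- and at least 41.3-fold. Primitive endoderm genes rose, with Gata6 higher by at least 5.95-fold and Sox17 by at least 4.48-fold against cells without Dox. Against cells without Dox 10 of 15 AP-1 and stress kinase targets and 5 of 13 NF-kB targets rose (adjusted p = 0.124 with an estimated correlation and adjusted p = 0.352 with an estimated correlation), and 5 of 18 naive pluripotency genes fell. Against cells without Dox 2606 genes were called, 1739 higher and 867 lower, and against EGFP cells 2625, 1753 higher and 872 lower. With no fold minimum the majority turned, with 2534 higher and 3425 lower against cells without Dox and 2529 and 3688 against EGFP cells. The arrays of the groups did not overlap in 51.4 and 50.6% of genes, where chance gives 10%. Folds were bounds for 650 and 765 calls, and 99 and 75 calls have no fold. With replicate number as a block 2812 and 2826 genes were called, of which 2599 and 2615 were also called without it.

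The same 2270 genes were called in the same direction against both controls, 1588 higher and 682 lower, and none in opposite directions. With no fold minimum these were 2294 and 2967. Independent lists of these sizes would share 211 and 52.4 genes. In 20 simulated data sets with no effect and the same shared arrays none was shared. These data sets averaged only 0.15 calls with against without Dox and 0 against EGFP cells. With so few calls they cannot show how much sharing the shared arrays alone create between lists of the sizes seen. Across genes the changes correlated at 0.97, where the shared arrays alone gave 0.50 in simulation. Their covariance was 0.727, and 0.0267 in simulation. Part of the excess may come from the shared arrays with Dox, which are too few to divide.

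Epidermal and cornified envelope genes were among the 10 that the naming rule gives for a rise. Against cells without Dox and EGFP cells, Crct1 rose at least 506- and at least 378-fold (against cells without Dox adjusted p = 4.03e-11), Lce3c at least 84.2- and at least 63.0-fold, and the skin protein gene Dmkn 110- and at least 102-fold. The annexin gene Anxa1 rose 333- and 395-fold (log2 change 8.38, SE 0.55, adjusted p = 3.22e-07 against cells without Dox). The mitochondrial carrier gene Slc25a24 rose at least 151- and at least 131-fold, the LIM domain gene Fhl2 108- and 119-fold, and the endothelin gene Edn2 at least 87.9- and at least 65.7-fold. Prss23 rose at least 105- and at least 78.4-fold and Thbs1 at least 104- and at least 75.7-fold, and both of these had fallen in null cells.

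Falls were smaller. The Ets family gene Spic fell 5.63-fold against cells without Dox (log2 change -2.49, SE 0.09, adjusted p = 1.79e-09) and 5.37-fold against EGFP cells, and Zmat4 6.42- and 6.26-fold. The pepsinogen genes Pga5 and Pgc fell at least 5.84- and at least 4.26-fold against cells without Dox, A2m at least 5.02-fold, the Fc receptor gene Fcgr2b at least 5.06-fold, the adhesion receptor gene Adgrd1 at least 4.81-fold, Adamtsl1 at least 4.33-fold and Npy at least 2.59-fold. Cd2 fell at least 3.64-fold by its brightest probe, while its other probe changed by 0.14. Outside the shared genes, Tmem211 fell at least 2.55-fold against cells without Dox and Serpina3i at least 3.50-fold against EGFP cells.

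Trophectoderm was the list with the largest median rise, 4.54 against cells without Dox. Of 12 measured genes 11 rose there (adjusted p = 4.81e-11, adjusted p = 0.057 with an estimated correlation) and 10 against EGFP cells (adjusted p = 8.71e-10, adjusted p = 0.0793 with an estimated correlation). Against cells without Dox Gata3 rose at least 56.7-fold, Krt7 at least 49.3-fold, Esx1 43.0-fold, Plet1 40.6-fold, Krt18 30.9-fold and Krt8 17.6-fold. Of 16 primitive endoderm genes 11 rose and 3 fell against cells without Dox (adjusted p = 8.18e-06, adjusted p = 0.0275 with an estimated correlation), and 12 and 2 against EGFP cells (adjusted p = 9.45e-06, adjusted p = 0.0265 with an estimated correlation). Their median change was 1.83 against cells without Dox, or 1.12 with genes near background at their bound. The collagen genes Col4a2 and Col4a1 rose 14.4- and 9.10-fold, Foxa2 at least 7.22-fold and Afp at least 2.70-fold, whereas Lama1 fell 2.37-fold, Sox7 1.86-fold and Hnf4a at least 1.95-fold.

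The naive pluripotency list fell by 0.54 at the median against cells without Dox (adjusted p = 8.18e-06, adjusted p = 0.0217 with an estimated correlation) and also against EGFP cells (adjusted p = 5.29e-05, adjusted p = 0.0265 with an estimated correlation). Of 18 genes 5 and 4 fell, or 5 in each adjusted over the list alone, and none rose. Against cells without Dox Fbxo15 fell 2.72-fold, Tcl1 2.37-fold, Tdh 1.87-fold, Esrrb 1.54-fold and Pecam1 1.53-fold. In the general pluripotency list 6 of 14 genes fell and 1 rose against cells without Dox (adjusted p = 0.00945, adjusted p = 0.302 with an estimated correlation), and 5 and 1 against EGFP cells (adjusted p = 0.0105, adjusted p = 0.272 with an estimated correlation). Dnmt3l fell 2.74-fold, Sox2 1.59-fold and Pou5f1 1.53-fold against cells without Dox. The formative and primed list was not called (adjusted p = 0.221 and 0.329). Against cells without Dox 5 of its 15 genes rose, or 6 adjusted over the list alone, such as Cdh2 9.30-fold and Dnmt3a 4.39-fold, and 2 fell, Sox3 2.02-fold and Otx2 1.95-fold. Against EGFP cells 4 rose and 2 fell.

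Of 15 AP-1 and stress kinase targets 10 rose in both comparisons, or 11 against cells without Dox adjusted over the list alone, and none fell. Adjusted p was 2.75e-06 and 3.38e-07, with adjusted p = 0.124 with an estimated correlation against cells without Dox and adjusted p = 0.0889 with an estimated correlation against EGFP cells. Gadd45g rose 34-fold, Dusp10 at least 14.5-fold, Atf3 7.29-fold and Fosl2 6.53-fold against cells without Dox. Of 13 NF-kB targets 5 and 6 rose and none fell (adjusted p = 0.00181 and 0.000746). These had adjusted p = 0.352 with an estimated correlation and adjusted p = 0.272 with an estimated correlation. The chemokine gene Ccl2 rose at least 23.6-fold, Tnfaip3 6.23-fold and Csf2 at least 5.62-fold. Among 21 ERK targets 7 rose in each comparison, and 3 fell against cells without Dox, or 4 adjusted over the list alone, and 1 against EGFP cells. The list was called against EGFP cells (adjusted p = 0.00494, adjusted p = 0.272 with an estimated correlation) and not against cells without Dox (adjusted p = 0.0654), and the difference was not tested. Ier3 rose 12.4-fold, Fosl1 10.6-fold, Phlda1 8.58-fold and Dusp4 6.65-fold, and Egr1 fell 2.45-fold, against cells without Dox.

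The p53 target list rose (adjusted p = 0.00891 and 0.00473, with adjusted p = 0.352 with an estimated correlation and adjusted p = 0.272 with an estimated correlation), with 6 of 16 genes higher in each comparison, such as Plk2 6.51-fold, Cdkn1a 1.82-fold and Mdm2 1.80-fold against cells without Dox. The proliferation list fell (adjusted p = 0.00181 and 0.000537, with adjusted p = 0.165 with an estimated correlation and adjusted p = 0.136 with an estimated correlation), although only 1 and 0 of its 16 genes were called. The fibroblast list rose with the lineage genes (adjusted p = 0.00389 and 0.00554, with adjusted p = 0.129 with an estimated correlation and adjusted p = 0.136 with an estimated correlation). In each comparison 7 of its 13 genes rose and 1 fell, or 8 rose against EGFP cells adjusted over the list alone. S100a4 rose 13.7-fold, Tagln 3.47-fold and Col1a1 2.98-fold, and Thy1 fell 2.58-fold.

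The other lists were not called against either control. Adjusted p was 0.411 and 0.481 for mesendoderm, 0.411 and 0.341 for neuroectoderm, 0.847 and 0.841 for the 2-cell-like list, and 0.0685 and 0.114 for germline genes. With replicate number as a block the germline list rose against cells without Dox (adjusted p = 0.0386), in a range of 0.00169 to 0.233 over all alternatives. Hand1 still rose at least 64.1-fold and Sox11 12.6-fold against cells without Dox. Adjusted p was 0.847 and 0.841 for interferon response, 0.445 and 0.404 for ATF4 targets, 0.603 and 0.453 for cholesterol synthesis, 0.445 and 0.453 for glycolysis and 0.817 and 0.633 for the cap-binding factors, in which Eif4g3 rose 3.15-fold. In the 2-cell-like list 1 gene rose and 1 fell against EGFP cells, and none of either adjusted over the list alone, and of 3 germline genes that rose there 2 remained.

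The Map3k3 array that lay in the slide row of the cells without Dox gave 2086 calls against them alone, 1420 higher and 666 lower. The spread in this test came from the other groups, and the lone array is assumed to vary like them. Within the other row of that slide Map3k3 against EGFP cells gave 2465.

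The reversal question asks which changes of null cells Map3k3 undoes. Of the 5526 genes called in null against wild-type cells, 1404 (25.4%) were called the opposite way in Map3k3 cells with against without Dox. Of these, 1076 had fallen in null cells and rose with Map3k3, where independent lists would share 347, and 328 had risen and fell, where they would share 158. With no fold minimum 1434 had fallen and 1917 had risen. Moving the same way were 117 genes that rose in both comparisons and 137 that fell in both, against 318 and 173 for independent lists. The pair of comparisons shares no arrays. Their changes correlated across genes at -0.50, and at -0.01 in simulation. The simulation held no effect and no background floor, so it covers noise alone. Genes near background in both null cells and Map3k3 cells without Dox can only be lower than in wild-type cells and rise with Map3k3. Neither the simulation nor the independent lists allow for that. Against EGFP cells, a comparison that shares the Map3k3 arrays with Dox, 1267 of the 1404 were reversed as well. Of all calls with against without Dox, 91.3% of the rises and 78.7% of the falls were also called there. Gadd45g, Prss23, Thbs1, Cdh2, Krt18 and Dnmt3a were among the genes that fell in null cells and rose with Map3k3. Of the 1404 genes 512 were still called against wild-type cells in the direction of the null cells, 672 were not called and 220 were called the opposite way.

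On the recovery score, Map3k3 cells with Dox reached 28.0 ± 3.38% (SD, n = 3), with single arrays at 26.4, 31.8 and 25.7%. Map3k3 cells without Dox lay at -4.81 ± 0.968% and EGFP cells at -2.88 ± 0.933%, with null arrays spread by 3.26 and wild-type arrays by 0.0874 around their ends of the scale. Map3k3 cells with Dox exceeded the 6 other transgenic arrays by 31.8 points (exact permutation test, two-sided, p = 0.0119, the smallest possible with 84 splits). Those splits ignore the replicate numbers. Equal numbers deviated together in these groups, so the arrays are not freely exchangeable. The 27 splits that take an array of each number allow no share under 0.037. The differences to Map3k3 cells without Dox and to EGFP cells, 32.8 and 30.8 points, each had exact p = 0.1, the smallest that 3 against 3 arrays allow. Over genes that had fallen in null cells the score was 33.8 ± 3.71%, and over genes that had risen 16.7 ± 2.98%.

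**Figure D3:**
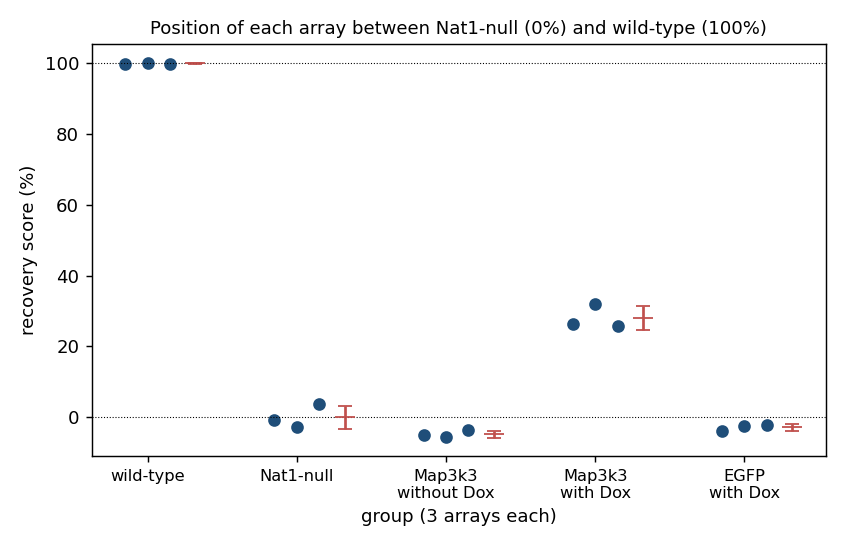
Recovery score in percent (y axis) of each of the 15 arrays in the 5 groups (x axis), from 0% at the mean of null arrays to 100% at the mean of wild-type arrays, with bars at the mean and standard deviation over 3 arrays. Map3k3 cells with Dox lie at 25.7 to 31.8% and the other transgenic groups at -4.81 and -2.88%.

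Map3k3 cells with Dox against wild-type cells show what differs from wild-type cells after induction. Genotype, transgene and Dox all differ in this comparison, so its calls are not all remains of the null state. The groups differed in 5530 genes, 2681 higher and 2849 lower, or 2368 and 1672 with probes above background on all 15 arrays, and did not overlap in 70.9% of genes, where chance gives 10%. Folds were bounds for 1285 calls and 13 have none. Of the calls in null against wild-type cells, 3616 were called in the same direction here. Independent lists would share 490 of the 1657 that rose and 569 of the 1959 that fell, and part of the excess may come from the shared wild-type arrays, which alone gave a correlation of 0.50 in simulation where 0.74 was seen. The covariance was 1.05, and 0.0266 in simulation. Eif4g2 was lower by 6.5-fold (adjusted p = 1.4e-08). The naming rule gives as rises those of Tlx2, at least 160-fold, Nkx6-3, 101-fold, the cornified envelope genes Lce3b and Lce3c, at least 35.8- and at least 34.7-fold, and the homeobox gene Hoxc9, at least 14.9-fold. Meg3 was lower by at least 819-fold, H19 by at least 580-fold, Snrpn by at least 266-fold, Mirg by at least 117-fold and Enpp2 by at least 73.7-fold. These groups share no slide. With slide as a block, where EGFP with Dox 3 is the only array that links the slides, 4424 genes were called, 2349 higher and 2075 lower.

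Of 13 NF-kB targets 12 were higher than in wild-type cells (adjusted p = 0.000282, adjusted p = 0.294 with an estimated correlation), as were 10 of 15 AP-1 and stress kinase targets (adjusted p = 0.00336, adjusted p = 0.294 with an estimated correlation). In the trophectoderm list 7 of 12 were higher, or 8 adjusted over the list alone, and 2 lower (adjusted p = 0.0205, adjusted p = 0.41 with an estimated correlation). Cholesterol synthesis was the fourth list to rise, with 4 of 17 genes (adjusted p = 0.0178, adjusted p = 0.41 with an estimated correlation). The formative and primed list fell, with 12 of 15 genes lower (adjusted p = 0.00856, adjusted p = 0.294 with an estimated correlation). So did neuroectoderm, with 9 of 14 lower (adjusted p = 0.0211, adjusted p = 0.294 with an estimated correlation), and the fibroblast list, with 9 of 13 lower (adjusted p = 0.00856, adjusted p = 0.294 with an estimated correlation). In the interferon list 6 of 8 were lower, or 7 adjusted over the list alone (adjusted p = 0.0471, adjusted p = 0.294 with an estimated correlation). Naive pluripotency, with 8 of 18 genes higher and 4 lower, was not called (adjusted p = 0.0655), nor were primitive endoderm (adjusted p = 0.0678) and ERK targets (adjusted p = 0.228).

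The remaining comparisons ask whether Dox or the transgenes change null cells by themselves. EGFP cells with Dox differed from null cells in 1 gene, the transcription factor gene Tfap2a, which rose 1.92-fold from -1.81 ± 0.04 to -0.87 ± 0.22 (log2 change 0.94, SE 0.09, adjusted p = 0.00456). At an unadjusted p under 0.05 limma counted 1095 genes, and the arrays did not overlap in 12.0% of genes, where chance gives 10%. No list was called, the lowest adjusted p being 0.118, shared by the germline, AP-1 and stress kinase and glycolysis lists. With replicate number as a block the germline list, whose median change was -0.26, fell (adjusted p = 0.014), and over all alternatives it ranged from 0.00448 to 0.58. Without EGFP with Dox 1 the lists of AP-1 and stress kinase targets, ATF4 targets and glycolysis were called too, with adjusted p = 0.0117, 0.0186 and 0.0361, each the lowest of a range up to 0.933. With replicate number as a block 1 gene was called over all arrays, and 13, 5 higher and 8 lower, over the 12 null-background arrays. A single EGFP array shared the slide of the null arrays and gave 25 calls against them, with the spread of the other groups, which says nothing of the other EGFP arrays.

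Map3k3 cells without Dox differed from null cells in 0 genes by limma, with 2216 at an unadjusted p under 0.05, a smallest adjusted p of 0.0674, and no overlap in 21.8% of genes, where chance gives 10%. With replicate number as a block, since equal numbers deviated together here, 42 genes were called, 14 higher and 28 lower, and 67 over the 12 null-background arrays. These groups share no slide, and with slide as a block, linked by EGFP with Dox 3 alone, 13 genes were called. The AP-1 and stress kinase list rose by 0.30 at the median (adjusted p = 0.000262, adjusted p = 0.494 with an estimated correlation), with 0 members called over all genes and 3 higher adjusted over the list alone. The next lowest adjusted p was 0.0577. The germline list, with a median change of -0.37, had 0.0226 with replicate number as a block, in a range of 0.00908 to 0.854. Other lists under 0.05 in some alternative were ERK targets (0.00822 to 0.817), NF-kB targets (0.0127 to 0.962) and ATF4 targets (0.0164 to 0.976). So were p53 targets (0.0263 to 0.906), trophectoderm (0.0328 to 0.982), proliferation (0.0328 to 0.921) and glycolysis (0.00822 to 0.858).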

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

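The list of imprinted genes, the tests of fibroblasts and of DNA methylation for these genes, the test of Dox itself and the test of sub-lines for the replicate numbers were chosen only after the result was seen.

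Probes without a gene symbol, which the comparisons above do not use, carried signal that differed between groups. In null against wild-type cells 2992 of 10851 such probes were called, 1823 higher and 1169 lower, and in Map3k3 cells with against without Dox 1436, 346 higher and 1090 lower. A probe placed on chromosome 14 from 77077374 to 77086910 (mm9) rose 59.3-fold in null cells (adjusted p = 4.67e-06), and one on chromosome 12 from 110842154 to 110883594 fell 27.8-fold. With Map3k3 a probe on chromosome 10 from 60473030 to 60535340 fell 4.82-fold and one on chromosome 4 from 129380903 to 129390686 rose 3.79-fold. What these probes measure was not analysed here.

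The first pattern weighed is the fall of imprinted genes in null cells, where 21 of 29 measured imprinted genes fell, 1 rose and 7 were not called. A difference between slides or slide rows is argued against, because the EGFP array on the slide and row of the wild-type arrays lay nearer the null mean in 100% of the 21 genes and in 97.2% of all calls. Of 22 genes of the class that a gain of DNA methylation at all germline control regions should silence 17 fell, as did 4 of 7 of the other class, but such a gain is argued against by the other 5, Mkrn3, Peg12, Zrsr1, Airn and Mcts2, whose 95% intervals exclude a 2-fold fall, although signal from related genes on those probes was not tested. Fibroblasts in the wild-type cultures may contribute and could not be excluded, since 9 of 13 fibroblast markers fell while the abundant collagen gene Col3a1 changed by 0.40 near the floor. Methylation at part of the control regions, and an effect of the lost gene itself, stay open and were not tested.

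The second pattern is the response to Map3k3 with Dox. Dox itself is argued against by the 2606 genes called with against without Dox, which were chosen without the EGFP and null arrays and whose median log2 change in their own direction was 1.13, and -0.0541 in EGFP cells with Dox against null cells. A slide row difference is argued against by 2242 response genes found without the Map3k3 array that shares its row with the cells without Dox. In that array 98.6% of them lay on the response side, with a median log2 change of 1.14 in their direction. The genes were chosen against the same mean of cells without Dox, so part of that share is built in. Splits of the 9 transgenic arrays gave as many response genes in 1 of 84, the real one, with 2270 against at most 2 in the others. Of the 27 splits that take an array of each number 1 gave as many, with at most 0 in the others. These are the smallest shares that 84 and 27 splits allow. The other splits also place Map3k3 arrays with Dox among the controls, which widens the spread. Chance is therefore argued against but not excluded. An effect of the Map3k3 transgene, is a hypothesis from the same data, and the transgene's own level was not measured.

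The third pattern is the deviation shared by arrays of equal number in the null-background groups. A difference between slides or rows is argued against, because 5 pairs of equal number that share neither had a mean correlation of 0.34 (0.193 to 0.617). A candidate explanation, the only biological one tested, is that the numbers mark sub-lines that lost different amounts of the Y chromosome and were carried through all 4 groups. Eif2s3y, a Y-linked gene, was among the genes first seen to follow the number, and Ddx3y, also Y-linked, had its order in 4 of 4 groups, while Uty had it in 6 of 8 cases, with 6 of its 24 readings well above background, and the X-linked Eif2s3x had it in 4 groups by 1 probe and in 0 by its other, so that signal shared between the X and Y copies is not excluded. Means over the groups were, for Ddx3y 0.30, 1.52 and -0.35, and for Eif2s3y 2.33, 3.23 and 1.13 for numbers 1, 2 and 3, where wild-type cells read 1.89 and 3.53.

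For single comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real and highest other counts were 5526 and 0 for null against wild-type cells, 2606 and 0 for Map3k3 with against without Dox, 2625 and 0 for Map3k3 against EGFP cells, and 5530 and 0 for Map3k3 with Dox against wild-type cells, each reached by 1 split. For EGFP against null cells they were 1 and 2, with 5 splits at 1 or more, and for Map3k3 cells without Dox against null cells 0 and 0 in all 10. Since equal numbers go together in EGFP and null cells, the 3 other splits that also part every pair of equal numbers compare best with the real one, and they gave 0 to 2 calls. For the reversal they were 1404 and 0, reached by 1 split.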

How the results depend on the processing

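The alternatives with slide row alone or with slide as blocks, within 1 slide or slide row, with the replicate block over the 12 null-background arrays, and without arrays numbered 2 were chosen only after the data were seen.

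Counts stayed within 1.5 times of the values above except as follows, and the cause was not tested. The 1 call in EGFP against null cells became 2 with normexp, 0 with the groups of the comparison alone, 0 at 2-fold, 21 with slide as a block, 3 with slide row, 12 with both, 13 with the replicate block over 12 arrays, 25 within slide 2 and 13 without arrays numbered 2. The 0 calls in Map3k3 cells without Dox against null cells became 2 with normexp, 14 with probes above background on all 15 arrays, 13 with slide as a block, 2 with slide row, 7 with both, 42 with the replicate block, 67 with the replicate block over 12 arrays and 5 without arrays numbered 2. With no fold minimum the majority direction turned, except in Map3k3 against wild-type cells. Counts were 9251 (5309 higher, 3942 lower) for null against wild-type cells, 5959 (2534, 3425) and 6217 (2529, 3688) for Map3k3 with Dox against cells without Dox and EGFP cells, 8910 (4442, 4468) against wild-type cells, 5261 (2294, 2967) response genes and 3351 reversed genes, of which 1434 had fallen and 1917 risen in null cells. At 2-fold they were 3293 (1130, 2163), 1509 (1203, 306), 1477 (1190, 287), 3231 (1384, 1847), 1334 (1097, 237) and 885 (780, 105). With probes above background on all 15 arrays Map3k3 with against without Dox had 1737 calls and 833 genes were reversed, and with slide and slide row as blocks 874 were reversed. With the replicate block null against wild-type cells had 5671 calls and Map3k3 with Dox against wild-type cells 5697, where equal numbers did not deviate together. It also called the interferon list in the first (adjusted p = 0.0321, range 5.07e-09 to 0.222) and 9 named-gene values. Besides the germline calls above no other list or named-gene call changed.

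In null against wild-type cells 47.8% of calls were rises, and 61.1% of 3938 with probes above background on all 15 arrays. Rises were 51% of 6356 with no detection filter and 50.7% of 4987 with slide row as a block. In Map3k3 with Dox against wild-type cells 48.5% were rises, 58.6% of 4040 with that filter and 60.8% of 7736 with no detection filter. Quantile normalization, normexp and the authors' values kept 89.1, 81.3 and 97.5% of the 5526 calls.

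Of 20 lists in each of the 4 comparisons with many calls 35 tests were called, 4 with an estimated correlation and 61 with fry, which does not compare a list with other genes. Values are adjusted p, with the other end of the range over all alternatives in parentheses. With an estimated correlation the naive and formative lists in null against wild-type cells had 0.0693 (4.54e-12) and 0.222 (2.05e-06), ERK targets against EGFP cells 0.272 (3.88e-05) and the formative list against wild-type cells 0.294 (9.92e-06). With fry, primitive endoderm in null against wild-type cells had 4.38e-05 (0.33), and the formative list and ERK targets with against without Dox 0.0251 (0.618) and 0.000138 (0.511). Against wild-type cells fry gave the naive list 5.86e-10 (0.294), ERK targets 0.000177 (0.706) and primitive endoderm 1.83e-06 (0.294). ERK targets with against without Dox had 0.0453 with normexp, and against EGFP cells 0.066 without arrays numbered 2. Against wild-type cells the naive list had 0.0463 with slide and 0.0462 with slide and slide row as blocks, primitive endoderm 0.0294 with no detection filter and the formative list 0.0521 with probes above background on all 15 arrays. The glycolysis list in Map3k3 cells without Dox against null cells reversed to 0.00822 (0.858) with slide and slide row as blocks. Mesp1 with against without Dox reversed to -0.029 with those blocks and within the slide row. The recovery difference without arrays numbered 2 was 29.4 points, and 31.8 with all arrays. Its exact permutation p = 0.0667 is the smallest that the remaining arrays allow.

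Leaving out each array in turn gave 5341 to 5513 calls for null against wild-type cells, 2431 to 2642 for Map3k3 with against without Dox, 2468 to 2649 against EGFP cells and 5296 to 5483 against wild-type cells. EGFP against null cells had 1 to 7, with 7 without null 1 or null 2 and 2 without any 1 of the EGFP arrays. Map3k3 cells without Dox against null cells had 0 to 2, with 2 without null 1 and 1 without null 2. Response genes were 2120 to 2282, reversed genes 1319 to 1421 and the recovery difference 29.7 to 32.9 points. Adjusted p of the naive, formative, ERK and primitive endoderm lists was 0.00213 to 0.00289, 0.00241 to 0.00401, 0.286 to 0.415 and 0.0556 to 0.0706 in null against wild-type cells. With against without Dox it was 4.45e-06 to 2.42e-05, 0.141 to 0.355, 0.0338 to 0.231 and 4.45e-06 to 2.16e-05, with ERK targets at 0.0338 without Map3k3 with Dox 3, 0.0395 without Map3k3 with Dox 1 and 0.0432 without Map3k3 without Dox 3. Against EGFP cells it was 3.32e-05 to 0.000168, 0.192 to 0.435, 0.00204 to 0.0329 and 4.98e-06 to 1.95e-05. Against wild-type cells it was 0.0491 to 0.0667, 0.00414 to 0.0145, 0.155 to 0.419 and 0.0564 to 0.0937, with the naive list at 0.0491 without wild-type 3.

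Of 356 named-gene calls 298 held under every alternative that measured them, other fold minimums left out. Background limits folds given as bounds, 1329 of 5526 calls in null against wild-type cells.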

Other observations

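The observations in this part were made after the values were seen, and the genes named here were chosen then.

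In Map3k3 cells with against without Dox 11 of 29 measured imprinted genes rose, 2 fell and 16 were not called. Dlk1 rose at least 12.3-fold, Igf2 at least 11.3-fold and Nap1l5 at least 1.42-fold, as these were not well above background on all arrays without Dox. On the log2 scale Nnat rose by 2.32, Peg10 by 1.95, Sgce by 1.52, Ndn by 1.35, Ascl2 by 1.22, Cdkn1c by 1.15, Peg12 by 0.72 and Plagl1 by 0.69. Mirg and Slc22a18 fell. Mirg read a mean of -4.43 without and -5.46 with Dox, against 2.36 in wild-type cells. The lowest values well above background on the arrays with Dox were -3.94 to -4.85, so its fall is a difference near background. Meg3, H19 and Snrpn, which fell in null cells, were not called. In null against wild-type cells Slc22a18 was the 1 imprinted gene that rose, 4.14-fold.

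The arrays numbered 2 in the null-background groups carried the highest Y-linked signal of the 3 numbers. Slc38a4, Ntrk3 and Unc93a also followed the number, and the standard deviation of Slc38a4 over 3 arrays was 1.95 to 4.63 in the null-background groups and 0.11 in wild-type cells. The imprinted genes Meg3 and Kcnq1ot1 had mean deviations of 1.85 and 1.37 on arrays numbered 1, near background. Meg3 was well above background in Map3k3 without Dox 1 (-2.13) and Map3k3 with Dox 1 (-3.78), and on no other null-background array. A link between the fall of imprinted genes and the number was not tested. Among the genes that rose with Map3k3, Crct1, Lce3c and Dmkn belong to the epidermis, and the Lce3b and Lce3c signals also exceeded those of wild-type cells.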
